A study of Arabidopsis thaliana with 9 samples.

How the data were processed

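Seeds of 3 *Arabidopsis thaliana* genotypes, Col-0 wild type (WT) and the loss-of-function mutants *nac25* and *nac1L*, were imbibed on agarose plates and collected after 12 h, with 3 biological replicates per genotype and 9 libraries in all, per the labels. RNA was extracted from whole seeds with phenol and chloroform, cleaned on a column and made into stranded libraries, per the labels' protocols. FastQC 0.11.5, TopHat2 2.1.0 and Cuffdiff 2.2.1.3 were used, per the submitters' processing notes. The genome build, the gene annotation and the normalization between libraries are not given in the sources used here.

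The deposited table holds the authors' pairwise comparisons and no value per library or genotype. For each of 33557 genes and 3 comparisons it gives a log2 fold, an unadjusted p-value, an adjusted q-value and a test status, per the file headers. The log2 fold was read as that of the second genotype over the first. For 20641 of 20643 genes with finite folds the 3 comparisons added up within 0.001. That sum would also hold with all signs reversed, so it does not check the direction. The lower values of NAC25 and NAC1L in the mutants go with this reading, although neither gene had a test. In the deposited fold column, 2222 cells read as infinity and 3122 hold a spreadsheet error, taken here as minus infinity, and for all 2672 genes concerned the resulting pattern of zeros across the 3 genotypes was a possible one. Such genes are described as listed at 0, without a fold. The smallest deposited p-value is 5e-05 and the smallest q-value 0.000463, so that values at this floor do not rank genes. The deposited q-values equal a Benjamini-Hochberg adjustment over all 54131 tests of the 3 comparisons together, within 5.27e-07. Of the deposited gene names, 23 had been turned into dates by a spreadsheet, and identifiers were used for these. Genes with too few reads (15303, 15382 and 15794 in *nac1L* against WT, *nac25* against WT and *nac25* against *nac1L*), with too many reads (17, 16 and 17) or with a failed test (4, 4 and 3) had no test.

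No depth, no level and no spread between replicates can be taken from these values, so no standard deviation, interval or detection limit is given. The deposited p-value of a gene reflects the precision of its fold, and genes with few reads have imprecise folds even where called. Reads of close copies, such as the Rubisco small subunit genes, small heat shock protein genes and the neighbouring GSTF6 and GSTF7, could have been divided between them by the authors' software.

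The test between genotypes was the authors' own. Before the data were examined the design provided for count or per-library values as well, and for the authors' q-value at or below 0.05 where neither was given. That last provision applied, and no further test between genotypes was made. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Identifiers were matched to the TAIR10.1 reference annotation for product names, annotation terms and transcript lengths (32809 matched). No coordinates are given, because the build behind the table is not named.

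Before the data were examined 15 gene lists with 252 genes were written down: 14 that fit a germinating seed and its tissues, and the pair of targeted genes. These were expansins, xyloglucan and mannan remodelling, gibberellin, abscisic acid and dormancy, storage proteins and oleosins, LEA proteins, lipid mobilisation, cell cycle, photosynthesis, heat shock, jasmonate and defence, and markers of endosperm, seed coat and embryo. The 4 endosperm markers with a test also stand in a wall or abscisic acid list. EXPA2 is also the expansin that the study's authors followed, so its inclusion is not independent evidence. For lists with at least 5 tested members, the calls in each direction were set against all other tested genes by a one-sided Fisher's exact test, and the list median against 10000 random lists of tested genes of the same size, two-sided, which allows no p below 0.0002. List medians are over members with a finite fold. These tests, and the Fisher tests of the added gene groups and terms, take genes as independent units. Members of a list can change together, so the p-values do not measure the spread between replicates. Matching random lists on expression was planned but needs levels, so lists matched on transcript length were drawn as an addition. Benjamini-Hochberg adjustment ran over 70 Fisher tests and, separately, over 35 median tests. Adjustment "over the list alone" was Benjamini-Hochberg over the deposited p-values of the list's tested members.

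Genes to be named were set by rule before the data were examined: the 10 largest increases and 10 largest decreases among called genes with a finite fold per mutant against WT, the 5 and 5 largest between mutants, up to 4 called members with the largest folds per list, and the 3 genes NAC25, NAC1L and EXPA2. The rule's minimum level and its log2(value + 1) scale could not be applied without levels. Members outside the rule are marked in the text as chosen after their values were seen. The locus of NAC1L is not given in the labels and was taken as AT3G12977.

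The overlap of the mutants' calls was set against that of independent lists and against 100 simulations of unchanged groups. In these a shared WT deviation and separate mutant deviations were drawn for each gene from the standard errors implied by the deposited fold and p-value. Since the median fold differed between comparisons, the folds were also centred on the median of tested genes, the p recomputed from the implied standard error (the fold divided by the normal quantile of its p, or the median standard error where p was at least 0.9) and adjusted over all comparisons. At the smallest p the implied standard error is an upper limit, which makes the recomputed p too large for genes whose fold shrinks on centring. A second version used the median standard error there where it was below that limit. Genes whose limit was already below the median kept it, so the second version cannot show how many of their calls were lost through it. Centring with the p recomputed in the first way was tested on simulated folds with an offset of -0.2. Of 200 genes changed by 2 on the log2 scale, 100% were recovered among 18179 genes simulated for *nac1L* against WT, 96% among 18085 for *nac25* against WT and 99.5% among 17719 for *nac25* against *nac1L*. Unchanged genes called fell from 678, 496 and 782 before centring to 9, 7 and 7 after it, in the same order. The simulated changes were few and equally often up and down, so they left the median at the offset. In the data 28.5% of tested genes were called in *nac1L* and 39.0% in *nac25*, most of them lower. Real change can then shift the median and be removed by centring, which the simulation does not test. The simulated change of 2 was also larger than most called folds. In the same order, the median log2 fold was -0.72, -0.77 and -0.48 for lower and 0.52, 0.57 and 0.45 for higher calls. Recovery of changes of that size was not tested. Other alternatives were a q of 0.01, a minimum fold of 2, centring before applying that minimum, and adjustment within each comparison alone. Annotation terms with at least 10 tested genes, cytosolic ribosomal protein genes and a list of nitrate-response genes were examined as additions after the data had been seen.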

Results

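RNA was sequenced from whole *Arabidopsis thaliana* seeds collected 12 h after the start of imbibition, when stored reserves are still in place and the embryo is preparing to grow through the endosperm that surrounds it. The 9 samples covered 3 genotypes, with 3 biological replicates each: the Col-0 wild type (WT) and the loss-of-function mutants *nac25* and *nac1L*, each of which lacks a transcription factor of the plant-specific NAC family. The comparisons asked which transcripts differed between either mutant and WT at this time, and whether the mutants differed from each other. All seeds were collected at 12 h, so dependence on a factor cannot be told apart from a lag of the mutants in germination. All folds and q-values of single genes are those of the authors' deposited table, which lists 33557 genes in 3 comparisons and gives no level per library or genotype. Sequencing depth and the spread between replicates were therefore unknown, and a gene was called higher or lower where its deposited q was at or below 0.05.

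The targeted genes were examined first. NAC25 (NAC025, AT1G61110) had a log2 fold of -3.97 in *nac25* and of -2.66 in *nac1L* relative to WT in the authors' deposited table. NAC1L, taken here as AT3G12977, had a log2 fold of -4.61 in *nac1L* and of -1.89 in *nac25* in the authors' deposited table. Each gene was thus lowest in the mutant named after it, but the authors' deposited table marks both genes as having too few reads for a test in all 3 comparisons, so neither the loss in the own mutant nor the lower value in the other was tested. EXPA2 (AT5G05290), a cell-wall-loosening expansin of the endosperm, was among the most strongly reduced transcripts in both mutants. By the authors' deposited table it was 18.5-fold lower in *nac1L* (log2 -4.21, q = 0.000463) and 29.5-fold lower in *nac25* (log2 -4.88, q = 0.000463), where 0.000463 is the smallest q the table holds. The direct comparison in the authors' deposited table also called EXPA2 lower in *nac25* than in *nac1L* (log2 -0.67, q = 0.000866).

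In *nac1L*, lower calls were enriched among wall-loosening, cell-cycle and photosynthesis genes, the last not after centring, and higher calls among late embryogenesis abundant (LEA), abscisic acid and heat shock genes. Of 18233 tested genes, 5203 were called, 1754 higher and 3449 lower in *nac1L*, and of these 157 and 1130 differed by at least 2-fold. Among the 10 largest reductions in the authors' deposited table were the xyloglucan-modifying enzymes XTH33 (log2 -5.95) and XTH31 (-5.34), the zinc finger gene ZFP4 (-5.44), the nitrate-regulated LBD39 (-5.27), the fatty acid desaturase ADS1 (-4.78) and the nitrate reductase NIA2 (-4.75). The largest increases in the authors' deposited table were AT5G35935 (log2 5.10, q = 0.024) and AT2G07090 (2.89, q = 0.0374), and the 10 largest included AT4G25830 (2.53), the cytochrome P450 gene CYP81D11 (2.49), the phosphate transporter gene PHT1-7 (2.37) and the ubiquitin ligase gene ATL33 (2.08).

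Expansins had the lowest median fold of the 14 lists (-2.52). Of 14 expansins tested, 11 were lower and 1 higher in *nac1L*, the same counts as when adjusted over the list alone (Fisher's exact test against all other tested genes, adjusted p = 2.26e-05 for lower calls). In the authors' deposited table EXPA14 (log2 -3.59), EXPA1 (-3.47) and EXPA8 (-3.03) were lower beside EXPA2, and the 1 member that was higher, EXLA1, was picked out after its value was seen. Among 22 genes of xyloglucan and mannan remodelling, 11 were lower and the remaining 11 did not pass, also 11 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00682). Besides XTH33 and XTH31 they included XTH9 (log2 -3.60) and XTH4 (-3.55) in the authors' deposited table. MAN7 was the only mannanase gene among them. The mannanase genes MAN1, MAN2, MAN5 and MAN6, named after their values were seen, were tested and did not pass.

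LEA and heat shock genes had enriched higher calls, and storage genes were called in both directions. Of 16 LEA genes, which protect the dry seed, 11 were higher and 5 did not pass, 12 being higher when adjusted over the list alone (Fisher's exact test, adjusted p = 4.09e-07). EM1 (log2 0.97), AT2G42560 (0.95) and AT3G22490 (0.63) were among the higher members in the authors' deposited table. Among 8 storage protein and oleosin genes 2 were higher and 2 lower, with the same counts when adjusted over the list alone, and neither direction was enriched (Fisher's exact test, adjusted p = 0.434 and 0.938). A further 5 genes of this list had too many reads for a test in either mutant against WT, so the result leaves them out. The albumin genes AT2S1 (log2 -2.09) and AT2S2 (-0.71) were lower and the oleosin genes AT3G01570 (0.44) and OLEO2 (0.40) higher in the authors' deposited table. Of 17 heat shock genes 7 were higher and 1 lower, as when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00478 for higher calls), with CLPB1 (HSP101, a protein disaggregase, log2 1.19) and HSP23.6 (1.26) higher and HSP17.6 (-1.57) lower in the authors' deposited table. The median of this list was 0.01 and was not set apart from random gene lists (permutation test, adjusted p = 0.615).

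Hormone genes were divided. Among 22 genes of abscisic acid and dormancy, 7 were higher and 3 lower, or 9 and 3 when adjusted over the list alone, and the higher calls were enriched (Fisher's exact test, adjusted p = 0.0175). In the authors' deposited table the dormancy-related MFT (log2 0.89) and the abscisic acid synthesis gene ZEP (0.70) were higher, whereas the regulator ABI4 (-1.37) and CYP707A2 (-1.07), which encodes an enzyme that breaks down abscisic acid, were lower. The third lower member was the phosphatase gene ABI1, named after its value was seen, whose call was lost after centring. The other higher members, also named after their values were seen, were AAO3, NCED9, ABI5 and the phosphatase genes HAB1 (log2 0.51) and AHG1 (0.41) in the authors' deposited table. Phosphatase genes thus went both ways. Of 25 gibberellin genes 4 were higher and 9 lower, or 6 and 9 when adjusted over the list alone, and the lower calls were not enriched (Fisher's exact test, adjusted p = 0.113). They included GA3OX1 (log2 -2.87) and GA3OX2 (-2.19), which encode enzymes of the last step of gibberellin activation, and the gibberellin-responsive GASA6 (-3.64) in the authors' deposited table. The DELLA repressor genes RGL1 (log2 -1.47), RGL3 (-1.14), RGA (-0.87) and GAI (-0.52), picked out after their values were seen, were lower as well in the authors' deposited table. The lower calls thus also held repressors of the gibberellin response. The 4 higher members, named after their values were seen, were GA20OX1, GA20OX2, GID1A and GID1C.

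Among 18 cell-cycle and DNA replication genes 9 were lower and 2 higher, as when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0166). The sliding clamp gene PCNA (log2 -2.51) and the replicative helicase genes MCM7 (-2.19) and MCM6 (-1.21) were lower in the authors' deposited table, whereas CYCB1-1 (0.95) and TSO2 (0.90) were higher. Of 14 photosynthesis genes 7 were lower and 1, LHCB4.1, picked out after its value was seen, was higher, or 8 and 1 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0371). Their median of -0.56, or -0.49 after centring, lay below random gene lists (permutation test, adjusted p = 0.00595). The Rubisco small subunit genes RBCS-3B (log2 -2.06) and RBCS-2B (-1.74) and the antenna gene LHCB1.3 (-1.84) were lower in the authors' deposited table. The RBCS genes are close copies whose reads the authors' software could have divided between them. Of 5 jasmonate and defence genes 3 were lower, as when adjusted over the list alone, without enrichment (Fisher's exact test, adjusted p = 0.146) but with a median of -1.62 that lay below random gene lists (permutation test, adjusted p = 0.00288), namely BGLU23 (log2 -3.15), TIFY9 (-1.62) and TIFY10A (-0.85) in the authors' deposited table. Among 13 genes of lipid reserve mobilisation only CSY2 (log2 -0.49) was called in the authors' deposited table, also when adjusted over the list alone. The members ICL, with too many reads, and MLS, with a failed test, were picked out after their status was seen. The result leaves both out.

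Tissue markers gave 3 lower calls among 8 embryo markers, as when adjusted over the list alone, without enrichment (Fisher's exact test, adjusted p = 0.434), namely SHR (log2 -2.78), LTP1 (-1.95) and PDF1 (-0.87) in the authors' deposited table. Of 4 endosperm markers tested, EXPA2 and the mannanase gene MAN7 (log2 -1.73) were lower in the authors' deposited table, also when adjusted over the list alone, and of 2 seed coat markers none was called in the authors' Cuffdiff comparison (0 at an unadjusted p below 0.05). After the folds were centred on the median of tested genes (-0.07), with the p recomputed, 2268 genes were higher and 2772 lower, the enrichment of photosynthesis genes among lower calls was lost (Fisher's exact test, adjusted p = 0.137) and that of gibberellin genes passed (adjusted p = 0.0303).

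**Figure D1:**
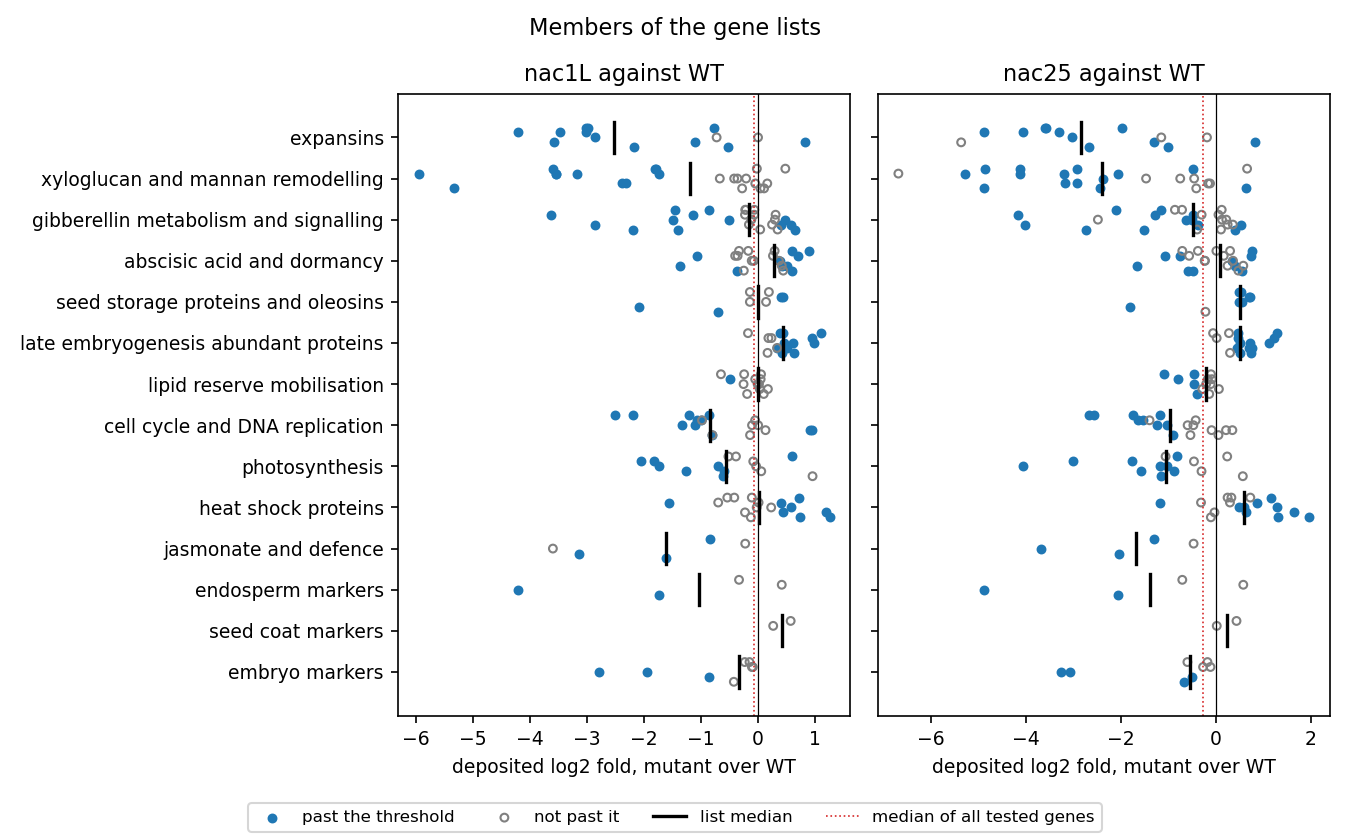
Log2 fold of each tested member of the 14 gene lists, *nac1L* over WT on the left and *nac25* over WT on the right, from the authors' deposited table, with filled points for members at or below the q threshold, open points for the others, black bars for list medians and a dotted line at the median of all tested genes (-0.07 and -0.27); members with an unbounded fold are not drawn. Expansin medians lie at -2.52 and -2.84, and those of LEA genes at 0.43 and 0.51.

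In *nac25*, wall-loosening, cell-cycle and photosynthesis genes had medians below those of random gene lists, and higher calls were enriched among LEA, storage, heat shock and abscisic acid genes. Of 18155 tested genes, 7086 were called, 1135 higher and 5951 lower in *nac25*, of which 124 and 2013 differed by at least 2-fold. The median log2 fold of all tested genes was -0.27, against -0.07 in *nac1L*. After centring on that median and recomputing the p, 2849 genes were higher and 2681 lower, and list medians are therefore also given relative to the shift. Among the 10 largest reductions in the authors' deposited table were ZFP4 (log2 -6.47), LBD39 (-6.10), NIA2 (-5.49), XTH4 (-5.28), the subtilase gene AT5G59130 (-5.00) and the pectin lyase-like gene AT3G15720 (-4.73). Among the 10 largest increases in the authors' deposited table were AT4G25830 (log2 2.46), CYP81D11 (2.26), the small heat shock protein genes HSP23.6 (1.97) and HSP26.5 (1.87), and the transporter gene ABCB9 (1.91).

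Of 14 expansins 10 were lower and 1, again EXLA1, was higher, or 11 and 1 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0175), with a list median of -2.84, or -2.58 relative to the shift. EXPA1 (log2 -4.06), EXPA9 (-3.60) and EXPA10 (-3.58) were lower beside EXPA2 in the authors' deposited table. Among the 22 genes of xyloglucan and mannan remodelling 13 were lower and 1 higher, XTH25, named after its value was seen, or 16 and 1 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0397), with a median of -2.40, or -2.13 relative to the shift. XTH31 (log2 -4.88), XTH18 (-4.86) and XTH9 (-4.13) joined XTH4 in the authors' deposited table. MAN7 was again the only mannanase gene called there.

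Of 16 LEA genes 12 were higher and 4 did not pass, 14 being higher when adjusted over the list alone (Fisher's exact test, adjusted p = 1.7e-10), with a median of 0.51, or 0.77 relative to the shift. ATECP31 (log2 1.28), AT2G42560 (1.23) and EM1 (1.11) were the members with the largest changes in the authors' deposited table. Of 8 storage protein and oleosin genes 6 were higher and 1 lower, as when adjusted over the list alone (Fisher's exact test, adjusted p = 1.73e-05), with a median of 0.51, or 0.78 relative to the shift, again without the 5 that had too many reads. The oleosin genes AT3G01570 (log2 0.72), OLEO2 (0.69) and OL3 (0.55) were higher and the albumin gene AT2S1 (-1.82) lower in the authors' deposited table. Among 17 heat shock genes 9 were higher and 1 lower, or 11 and 1 when adjusted over the list alone (Fisher's exact test, adjusted p = 3.05e-06), with a median of 0.59, or 0.86 relative to the shift. HSP23.6, CLPB1 (log2 1.64), the cytosolic chaperone gene HSP81-1 (1.31) and HSP17.7 (1.29) were higher, and HSP17.6 (-1.17) was lower in the authors' deposited table.

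Of 22 abscisic acid and dormancy genes 5 were higher and 5 lower, or 6 and 5 when adjusted over the list alone, and the higher calls were enriched (Fisher's exact test, adjusted p = 0.0397). The median was 0.09, or 0.36 relative to the shift, and centring gave 10 higher and 2 lower members. MFT (log2 0.76) and ZEP (0.73) were higher and ABI4 (-1.66) and CYP707A2 (-1.07) lower in the authors' deposited table, as was the synthesis gene NCED5 (-0.76). The other called members, named after their values were seen, were ABI5, ABI2 and AHG1 on the higher side and ABI1 and PP2CA on the lower. The calls of NCED5, ABI1 and PP2CA were lost after centring. Among 25 gibberellin genes 11 were lower and 2, GA20OX2 and GID1A, named after their values were seen, were higher, or 12 and 3 when adjusted over the list alone, without enrichment (Fisher's exact test, adjusted p = 0.421), and 7 were lower after centring. GASA6 (log2 -4.17), GA3OX1 (-4.02), GA3OX2 (-2.73) and the DELLA repressor gene RGL1 (-2.09) were lower in the authors' deposited table. So were the DELLA genes RGL3 (log2 -1.29), RGA (-1.16), GAI (-0.62) and RGL2 (-0.50), picked out after their values were seen.

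Of 18 cell-cycle genes 9 were lower, or 12 lower and 1 higher when adjusted over the list alone, and 7 were lower after centring (Fisher's exact test, adjusted p = 0.275 before and 0.0361 after centring). Their median of -0.96, or -0.70 relative to the shift, lay below random gene lists (permutation test, adjusted p = 0.001). PCNA (log2 -2.68), MCM7 (-2.57) and MCM6 (-1.75) were lower in the authors' deposited table, with the call of MCM7 lost after centring. Of 14 photosynthesis genes 9 were lower, or 10 when adjusted over the list alone and 7 after centring (Fisher's exact test, adjusted p = 0.0542 before and 0.00814 after centring). Their median of -1.04, or -0.78 relative to the shift, lay below random gene lists (permutation test, adjusted p = 0.001). RBCS-2B (log2 -4.05), RBCS-3B (-3.01) and LHCB1.3 (-1.76) were lower in the authors' deposited table, with the same caution about reads shared between RBCS copies. Of 5 jasmonate and defence genes 4 were lower, or 5 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.13 before and 0.00814 after centring). The median of -1.67 over the 4 with a finite fold, or -1.41 relative to the shift, lay below random gene lists (permutation test, adjusted p = 0.0107). BGLU23 (log2 -3.67), TIFY9 (-2.05) and TIFY10A (-1.30) were among them, and PR1, named after its value was seen, was listed at 0 in *nac25* in the authors' deposited table.

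Among 13 genes of lipid reserve mobilisation 5 were lower, or 6 when adjusted over the list alone, without enrichment (Fisher's exact test, adjusted p = 0.914), and their median of -0.20 became 0.06 relative to the shift. CSY2 (log2 -0.79), PMDH2 (-1.09), SDP6 (-0.47) and ACX2 (-0.46) were lower in the authors' deposited table, together with SDP1, named after its value was seen. After centring 2 were still called, the calls of SDP6, ACX2 and SDP1 being lost. ICL and MLS again had no test. Of 8 embryo markers 4 were lower, or 5 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.559), with LTP1 (log2 -3.25) and SHR (-3.06) lowest in the authors' deposited table, and PDF1 and PLT1 no longer called after centring. EXPA2 and MAN7 (log2 -2.06) were the 2 lower genes among 4 endosperm markers in the authors' deposited table, or 3 lower and 1 higher when adjusted over the list alone, and no seed coat marker of 2 was called in the authors' Cuffdiff comparison (0 at an unadjusted p below 0.05).

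The calls of the mutants overlapped. Among 18109 genes tested in both, 3297 were lower in both and 940 higher in both, against 1133 and 109 for independent lists of the same sizes and at most 24 and 32 in 100 simulations of unchanged groups with shared WT libraries. Unchanged groups give few calls, so the simulated counts do not represent lists of these lengths, and independent lists leave out the shared WT. Neither value tells how much overlap the shared controls would give lists this long. After centring with the p recomputed, 2141 genes were lower in both and 1869 higher in both. Of the genes lower in *nac1L*, 95.6% were also lower in *nac25*, and of those lower in *nac25*, 55.4% were also lower in *nac1L*. The corresponding shares of higher genes were 53.9% and 83.4%. These shares depended on the scaling, and after centring were 77.2% and 79.9% for lower and 82.8% and 65.9% for higher genes, in the same order. Across 17555 genes, which are not independent replicates, the log2 folds had a Pearson correlation of 0.886 and a Spearman correlation of 0.881, with a simulated Pearson correlation of 0.484. The covariance was 0.336 against 0.0486 simulated, a difference of 0.288. Both mutants were compared with the same WT libraries, which could not be split without values per library. The simulation includes a shared WT deviation of the size of the implied standard errors. A larger deviation of the WT libraries would still add to the excess and was not tested. Across genes the folds also followed transcript length (Spearman's rho 0.24 in *nac1L* and 0.22 in *nac25* against WT), and all 35 tests of list medians came out alike with random lists matched on length.

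**Figure D2:**
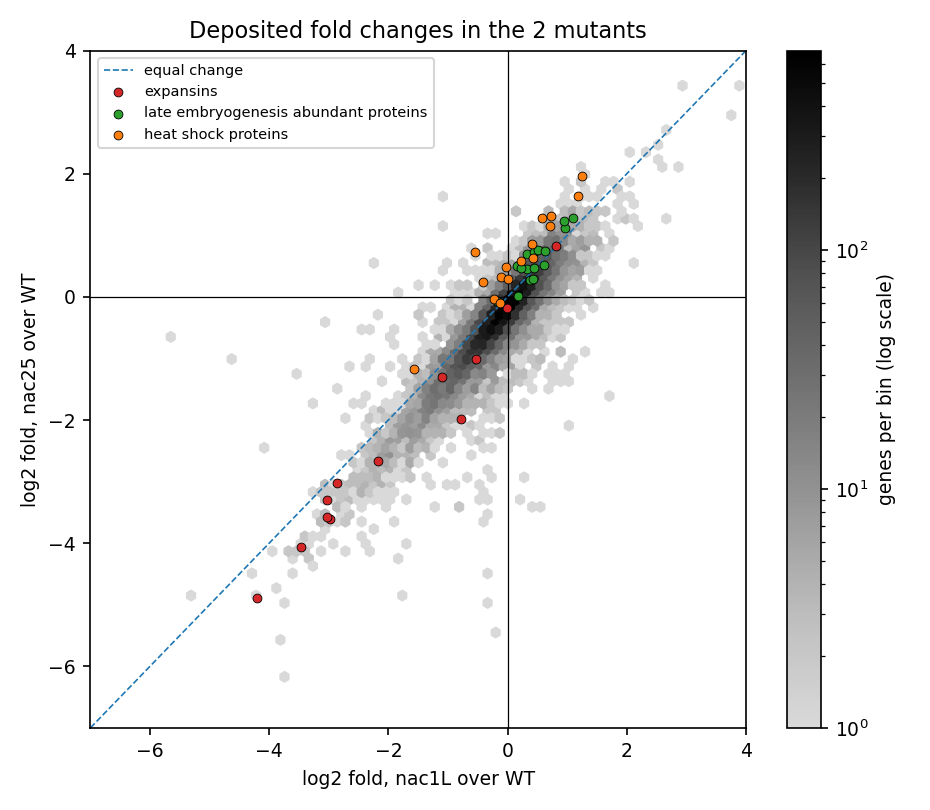
Log2 fold in *nac1L* over WT (horizontal) and in *nac25* over WT (vertical) from the authors' deposited table for 17555 genes with a finite fold and a test in all 3 comparisons, as grey bins of gene number on a log scale, with members of 3 gene lists as coloured points and a dashed line of equal change. Most genes lie along the line and somewhat below it, EXPA2 is the lowest expansin point at -4.21 and -4.88, and heat shock genes lie on or above the line.

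The direct comparison asked whether the mutants differed. Of 17743 tested genes 2186 were called, 108 higher and 2078 lower in *nac25* than in *nac1L*, with 13 and 167 of them at least 2-fold. The median fold of all tested genes was -0.20, and after centring on it and recomputing the p 749 genes were called, 473 higher and 276 lower. Adjusting the deposited p within this comparison alone left 965 calls, 64 higher and 901 lower. Single genes with large differences included HEI10 (AT1G53490, log2 2.58), a gene of meiotic recombination that was 8.15-fold lower in *nac1L* than in WT in the authors' deposited table, and the terpene synthase gene TPS09 (1.53). The largest reductions in *nac25* relative to *nac1L* in the authors' deposited table were AGP12 (log2 -4.10), the lectin gene AT3G16530 (-3.31), SOT13 (-3.25), AT5G33395 (-3.24) and CYP706A1 (-3.23).

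Of 16 heat shock genes 10 were higher in *nac25* than in *nac1L*, or 11 when adjusted over the list alone (Fisher's exact test, adjusted p = 2.48e-17), and 14 were higher after centring. They included HSP25.3 (log2 1.27), HSP23.6 (0.71) and HSP17.7 (0.71) in the authors' deposited table. The Fisher test takes these genes as independent although they can change together, so its p does not measure the spread between replicates. Of 9 storage protein and oleosin genes 4 were higher, or 6 when adjusted over the list alone (Fisher's exact test, adjusted p = 2.8e-06), and 9 after centring, while 4 others had too many reads for a test. In the authors' deposited table these were CRB (log2 0.68), OL2 (0.64), AT2S2 (0.49) and OL3 (0.41). Of 16 LEA genes 2 were higher, EM6 (log2 0.37) and M17 (0.34) in the authors' deposited table (Fisher's exact test, adjusted p = 0.0194), 0 when adjusted over the list alone and 7 after centring.

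Of 12 expansins 7 were lower in *nac25* than in *nac1L*, as when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00121), and 4 were after centring, with EXPA4 (log2 -1.20) lowest in the authors' deposited table. Of 20 genes of xyloglucan and mannan remodelling 8 were lower and 1, XTH25, named after its value was seen, was higher, or 11 and 1 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00762), and 4 were lower after centring. XTH18 (log2 -3.07), XTH24 (-2.15), XTH8 (-1.69) and XTH22 (-1.11) were the called members with the lowest folds in the authors' deposited table. Of 13 photosynthesis genes 5 were lower, or 6 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0463), and 2 after centring (adjusted p = 0.0534). Their median of -0.39, or -0.18 relative to the shift, lay below random gene lists (permutation test, adjusted p = 0.0183). RBCS-2B (log2 -2.31), LHCA1 (-1.15), RBCS-3B (-0.95) and RBCS-1A (-0.54) were lower in the authors' deposited table, together with RCA, named after its value was seen. The calls of LHCA1, RBCS-1A and RCA were lost after centring.

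Among 16 cell-cycle genes TSO2 (log2 -0.69), CYCB1-1 (-0.60) and MCM2 (-0.52) were lower in *nac25* in the authors' deposited table (Fisher's exact test, adjusted p = 0.627), 2 genes being lower when adjusted over the list alone. The cell-cycle median of -0.37, or -0.17 relative to the shift, lay below random gene lists (permutation test, adjusted p = 0.0153). Of 25 gibberellin genes GA3OX1 (log2 -1.15), GASA6 (-0.53) and RGL2 (-0.38) were lower in the authors' deposited table, 3 also when adjusted over the list alone. The calls of GASA6 and RGL2 were lost after centring. No abscisic acid or dormancy gene of 22 was called in the authors' Cuffdiff comparison (2 at an unadjusted p below 0.05), nor was a seed coat marker of 2 (0 at an unadjusted p below 0.05). In the authors' deposited table LACS6 (log2 -0.31) was the called gene of lipid mobilisation, TIFY10A (-0.45) that of jasmonate and defence and EXPA2 that of the endosperm markers, while the embryo markers LTP1 (-1.30) and PDF1 (0.37) went opposite ways. Adjusted over the list alone, 0 of 13 lipid, 1 of 4 jasmonate and defence, 2 of 4 endosperm and 2 of 7 embryo genes passed, and the calls of MCM2, LACS6 and TIFY10A were lost after centring. The lipid genes ICL and MLS had too many reads for a test between mutants.

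**Figure D3:**
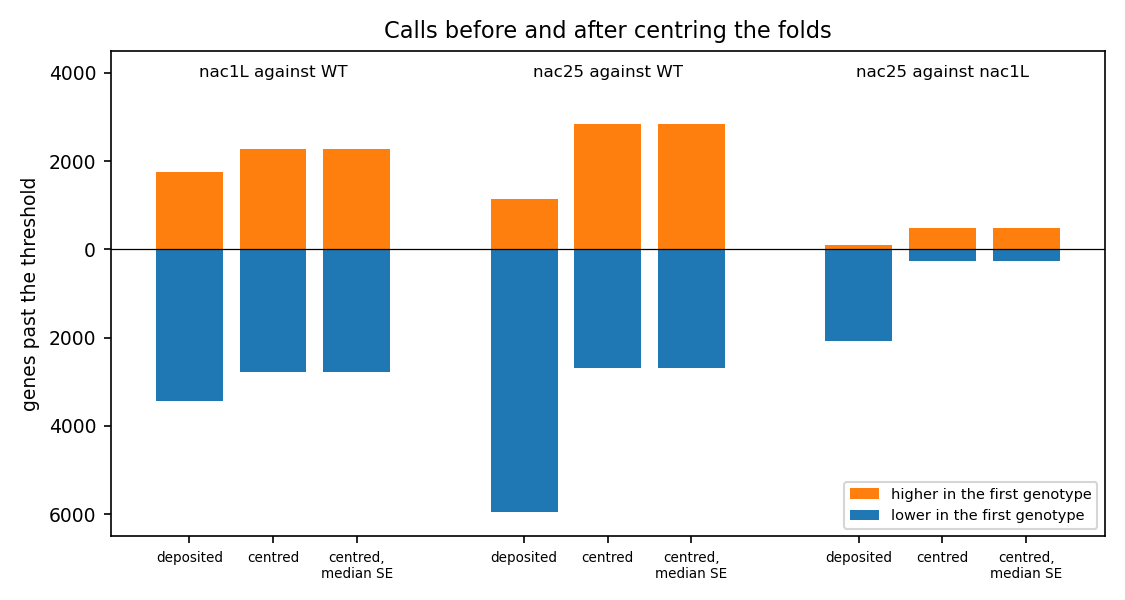
Number of genes at or below the q threshold in each comparison, higher (orange, above 0) and lower (blue, below 0) in the genotype named first, as deposited by the authors and after centring the folds with the p recomputed in both ways described for the processing. Higher and lower calls number 1135 and 5951 in *nac25* against WT as deposited and 2849 and 2681 after centring.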

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

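The share of lower calls after centring was set out as a test before its result was seen, and the tests of larger folds and of transcript length were chosen after. The results in this part stand out because the direct comparison of the mutants tested a difference between their responses and passed. For the genes called in opposite directions that pass was nearly fixed by their selection.

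In all, 2186 genes differed between *nac25* and *nac1L*, and 95.1% of them were lower in *nac25*. Adjusted within this comparison alone, 965 passed. After centring, 36.8% of the calls were lower, within the bounds set beforehand for an offset. Centring itself pushes the calls towards balance, however, so this share decides nothing, and for the calls as a whole an offset in scaling between genotypes and a true lower level cannot be told apart without library sizes or levels. Among the 90 calls of at least 2-fold after centring, 73 (81.1%) were lower in *nac25*, which argues against the offset as the whole cause for these larger folds. The bound for this share was set after the data were seen and was passed only narrowly, so the argument is weak. A trend with transcript length is argued against by a Spearman's rho of 0.0246 across genes. A biological difference between the mutants stays open.

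The direct comparison passed for 7 genes that were called in opposite directions in the mutants, all named after their values were seen. Since the folds add up across comparisons, such genes differ between mutants by more than either fold against WT. Their pass was thus nearly fixed by the selection and is not separate evidence. By the authors' deposited table, 6 of them were higher in *nac1L* and lower in *nac25*, with a log2 fold of *nac25* over *nac1L* of -3.31 for the lectin gene AT3G16530, -2.13 for the peroxidase gene PER52, -2.11 for the glutathione S-transferase gene GSTF7, -1.96 for the pirin gene PRN1, -1.81 for GSTF6 and -1.78 for the berberine-bridge-like gene AT1G26420. The seventh, AT1G67105, went the other way with 1.37 in the authors' deposited table. GSTF6 and GSTF7 are neighbouring close copies and count as uncertain where reads are shared. After centring with the p recomputed, AT1G26420 and PRN1 were no longer called in *nac25* and AT1G67105 no longer in *nac1L*, which left 4 of the 7 with opposite calls.

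EXPA2 was lower in *nac25* than in *nac1L* (log2 -0.67 in the authors' deposited table). Calls between the mutants were enriched for 7 expansins and 8 genes of xyloglucan and mannan remodelling that were lower in *nac25*, for 5 photosynthesis genes that were lower, and for 10 heat shock genes, 4 storage protein and oleosin genes and 2 LEA genes that were higher in *nac25*. After centring the photosynthesis genes were no longer enriched (2 genes, Fisher's exact test, adjusted p = 0.0534). The other lists stayed enriched, but with other counts: 4 expansins and 4 genes of xyloglucan and mannan remodelling were lower, and 14 heat shock, 9 storage and 7 LEA genes were higher. As deposited, 0 LEA genes passed when adjusted over the list alone.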

How the results depend on the processing

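The settings with a recomputed p, those adjusting within a comparison alone, the centring of the folds of NAC25 and NAC1L and the length-matched random lists were chosen after seeing the data, and the others before. No paired analysis was possible because the table holds no values per library. For the same reason DESeq2, the pseudocounts, the stricter level filter, the replicate block, leaving out replicates, fits of only the compared genotypes, set tests with an estimated correlation and other splits of the samples were not run, and a run without a filter would change nothing, since q-values exist only for tested genes. Depth limits are unknown. Length-matched random lists gave the same result for all 35 list medians. Centring moves a list and its random lists alike, so it cannot change the test of a median, but it turned the sign of 5 medians, none of which was set apart from random lists: storage in *nac1L* (to 0.0613), lipid mobilisation in *nac1L* (0.0549) and *nac25* (0.0622), and abscisic acid (0.0583) and embryo markers (0.0276) between mutants. EXPA2 kept its direction and side of the threshold in all settings run for it. In this part counts are given as higher and lower unless named as totals, and the cause was not tested except where a stricter threshold or minimum fold leaves fewer genes by construction.

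With a q of 0.01, 1009 genes were higher in *nac1L* and 750 in *nac25*, 576 in both, and 773 differed between mutants (60 and 713). With a minimum fold of 2 the totals were 1287 (157 and 1130) for *nac1L*, 2137 (124 and 2013) for *nac25* and 180 (13 and 167) between mutants. Centring before that minimum gave 1228 (202 and 1026), 1693 (320 and 1373) and 122 (15 and 107). Adjusting within the comparison alone left 965 between mutants (64 and 901). Centring with the p recomputed gave 2849 and 2681 for *nac25*, 749 in total (473 and 276) between mutants, 2141 genes lower in both mutants and 1869 higher in both. With the median standard error used at the smallest p where it was below the upper limit, the values were 2849 and 2690 for *nac25*. Between mutants they were again 749 (473 and 276). Genes with a limit below the median kept it, so these near-equal counts do not check the loss of calls at the smallest p.

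After centring, the untested log2 folds were -2.60 for NAC25 and -4.54 for NAC1L in *nac1L*, and -3.70 and -1.62 in *nac25*. Centring with the p recomputed brought the enrichment of lower calls past the threshold for 9 gibberellin genes in *nac1L* (Fisher's exact test, adjusted p = 0.0303) and, in *nac25*, for 7 cell-cycle genes (0.0361), 7 photosynthesis genes (0.00814) and 4 jasmonate and defence genes (0.00814). It ended that of photosynthesis genes in *nac1L* (5 genes, 0.137) and between mutants (2 genes, 0.0534).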

Other observations

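The annotation terms, the ribosomal protein genes and the test of nitrate-response genes in this part were chosen after the data had been seen. For nitrate-response genes the tests of length and scaling were set out before their results were seen.

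Protein synthesis was the annotation term with the smallest p among lower calls in both mutants. Of 365 tested genes annotated with translation, 212 were lower in *nac1L*, against 19.1% of other annotated genes (Fisher's exact test, adjusted p = 3.55e-55 over 1362 tests), and 301 of 364 were lower in *nac25* (33.1% of others, adjusted p = 2.56e-78). For ribosome biogenesis 69 of 100 genes were lower in *nac1L* (Fisher's exact test, adjusted p = 3.08e-23) and 90 of 100 in *nac25* (adjusted p = 4.01e-28). Both terms stayed enriched after centring, with adjusted p of 1.96e-42 and 1.34e-18 for translation in *nac1L* and *nac25*. Genes for charging transfer RNAs with amino acids were lower in *nac25* (26 of 30, Fisher's exact test, adjusted p = 8.82e-07), but not after centring (6 of 30). Genes responding to karrikin, a germination stimulant in smoke, were lower in both mutants (32 and 38 of 66, Fisher's exact test, adjusted p = 3.65e-05 and 0.00827), also after centring (29 and 31).

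On the higher side, the terms response to heat (17 of 54 in *nac1L*, 15 of 54 in *nac25*), response to hydrogen peroxide (7 of 12 in each) and response to high light intensity (8 of 17 in each) were enriched in both mutants, with adjusted p between 8.92e-05 and 0.00569 by Fisher's exact test, and after centring all but response to hydrogen peroxide in *nac25* (adjusted p = 0.0507) stayed enriched. Response to abscisic acid stimulus was enriched in both mutants as deposited (14 and 11 of 53, Fisher's exact test, adjusted p = 0.022 and 0.0233), but not after centring (adjusted p = 0.074 and 0.0512). Response to heat was also enriched among genes higher in *nac25* than in *nac1L* (11 of 52, Fisher's exact test, adjusted p = 1.31e-12). The median log2 fold of this term was -0.18, close to the -0.20 of all tested genes, so the enrichment rests on part of its genes. The heat, hydrogen peroxide and high light terms can share genes with each other and with the heat shock list. They need not be separate observations. Oxidation reduction genes were enriched among higher calls as well (58 of 352 in *nac1L*, Fisher's exact test, adjusted p = 0.00288, and 53 of 351 in *nac25*, adjusted p = 4.45e-07). Of 61 genes of the mitochondrial genome 9 were higher and 3 lower in *nac1L*, and 4 higher and 2 lower in *nac25*, with medians of 0.48 and 0.29 that were not tested. Of the 3 genes on each side of AT3G12977 in locus order, 2 were higher and 1 lower in both mutants and 1 was higher in *nac1L* alone, whereas of those beside NAC25, of which 2 had a test, none was called.

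Cytosolic ribosomal protein genes were lower as a group, 124 of 168 in *nac1L* and 158 of 168 in *nac25*, with medians of -0.44 and -0.69. These transcripts are short, and across genes the fold followed transcript length (Spearman's rho 0.24 in *nac1L* and 0.22 in *nac25*), but the group's median lay at percentile 0 of length-matched random lists in both mutants, which argues against that trend as the whole cause, the difference from the matched median being -0.22 and -0.24. An offset in scaling would move random lists alike, and the median also lay at percentile 0 of these in both mutants. After centring 63.1% of the genes were still called lower in *nac1L*, whereas 46.4% were in *nac25*, where offset and gene-specific change cannot be told apart for single genes because the share fell between the bounds, which were set after the data were seen. Both shares may be too low, because the implied standard error of genes at the smallest p is an upper limit. The second version of centring gave 47.0% in *nac25* but keeps that limit where it is below the median. For the group, lower calls stayed enriched in *nac25* after centring (78 of 168, Fisher's exact test, p = 9.16e-23), which argues against an offset as the whole cause. A lower ribosomal programme in both mutants remains a hypothesis, as does a lag of the mutants behind WT in the course of germination, which 1 time point leaves untested.

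NIA2, LBD39 and HHO3 (AT1G25550), seen first among the strongly reduced genes, respond to nitrate in seedlings. A candidate explanation is a reduced nitrate response in both mutants. Of 14 tested members of a nitrate-response list that had not been seen first, 7 were lower in both mutants, against 3290 of 18095 other genes (Fisher's exact test, p = 0.00682), including the nitrite reductase gene NIR1 (log2 -3.08 in each mutant) and NIA1 (-2.17 and -2.18) in the authors' deposited table. Taken singly, lower calls were enriched in *nac1L* (Fisher's exact test, p = 0.00847) but did not pass in *nac25* as deposited (8 of 14, p = 0.0524, or 0.0107 after centring). The nitrate transporter gene NPF6.3 was higher in both (log2 0.49 and 0.48) in the authors' deposited table. A transcript length trend is argued against by a median at percentile 0 of length-matched random lists in both mutants, and an offset in scaling by the 6 members still called lower in both after centring. Shared WT libraries can raise such an overlap, and a difference in seed nitrate between seed batches was not tested.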
